A study of Homo sapiens with 8 samples.

How the data were processed

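RNA was extracted from HTR8/SVneo cells with TRIzol and libraries were made from poly(A)-enriched RNA with oligo(dT) beads and PCR, per the labels' protocols. The groups were 4 control and 4 BMP8B libraries, taken from the sample labels, which also give the 24 h of treatment; the dose of BMP8B is not given in the sources used here. The authors deposited one table of FPKM values per gene and library, with a gene symbol and a gene type. The aligner, the counting tool, the genome build, the annotation and the handling of strand and of fragments shared between genes are not given in the sources used here, and no coordinates are printed for that reason. FPKM divides by gene length and by the library's fragment total, so a rise in abundant genes lowers all others, and it keeps any bias of the library with GC content or length.

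The table held 29458 rows, of which 1921 were at 0 in every library. A further 26 rows carried a calendar date in place of a gene symbol, as spreadsheets write for symbols such as those of septins, and were never named. Numbered suffixes marked 1606 rows as additional copies of a symbol, and 426 tested rows belonged to a symbol with more than 1 row. For a named gene or a list member the row with the highest mean was used, and its level is uncertain because fragments may be split between copies. Mitochondrially encoded protein genes were not analysed here.

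FPKM values of a gene rise in steps of 1 fragment. The lengths of 774 microRNA and tRNA genes in a RefSeq gene table gave each library's fragment total from these steps, and every one of the 27537 rows above 0 then came out as whole fragments within 0.02 in all 8 libraries. The recovered fragments summed to 99.919% to 99.923% of the totals, which were 14.28, 14.95, 14.79 and 15.05 M (M, the SI prefix mega) in control replicates 1 to 4 and 14.88, 16.60, 16.26 and 14.92 M in BMP8B replicates 1 to 4. On simulated data 99.6% of 500 genes were recovered exactly. The simulated genes were longer than the small RNA rows named below, so this share does not cover those rows. Recovered fragments served for depth, counting intervals and added checks. The lowest chi-square per degree of freedom between 2 libraries, over 13069 genes with at least 200 fragments in all, was 1.983, above sampling noise, so no library was treated as a duplicate. It was 2.003 between BMP8B replicates 1 and 3 and 3.967 between BMP8B replicates 2 and 4. Across these 2 pairs it was 6.597 to 15.832, against 13.131 to 41.48 between control and BMP8B libraries.

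Genes with a mean of at least 0.5 FPKM over the 8 libraries (13937) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with group as the only term, empirical Bayes with a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates changes of low genes; folds are ratios of mean FPKM. On simulated counts for the BMP8B against control comparison (13937 genes), the test recovered 22.4% of genes changed 1.25-fold, 85.1% of those changed 1.5-fold and 95.5% of those changed 2-fold, and called 7 of 13737 unchanged genes. Only 67, 67 and 66 genes were changed at these folds. With a simulated GC slope many more unchanged genes were called (45.8%, below), so these rates need not carry over to the real libraries.

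Before the data were examined, 40 gene lists were fixed from general knowledge of BMP signalling, trophoblast and common cell programmes. The 37 with at least 5 tested members were tested with camera at a preset correlation of 0.01 (two-sided, adjusted over the lists), and again with an estimated correlation and with fry. Named genes followed a rule fixed at the same time. It took the 10 largest and 10 smallest log2 changes among called genes whose groups did not overlap and whose mean reached 1 FPKM in one group, always BMP8B, ID1, ID2, ID3, SMAD6, SMAD7, BMPR1A, BMPR2 and ACVR1, and up to 4 members with the smallest p of each of the 20 lists discussed. A ranking of protein-coding genes alone was added after the values were seen, since small RNA rows filled much of the first part.

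GC content came from the longest GENCODE 29 transcript of each symbol and was found for 12962 tested genes (93%); the build behind the deposited values may differ. A spline of each library's deviation on GC content and log length was subtracted as an added alternative. On simulated values with a GC slope in the BMP8B libraries (12962 genes), 45.8% of unchanged genes were called before this step and 0.1% after it, and 100% of 200 changed genes were recovered. Matched random lists were drawn within bins of GC content, length and mean expression.

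Alternatives fixed before were pseudocounts of 0.1 and 0.5, no filter and filters at 1 and 5 FPKM, TPM, median-of-ratios and quantile scaling, other variance models, array weights, a block for the replicate number, stricter thresholds, camera with an estimated correlation, fry, Spearman correlation and leaving out each library. Alternatives chosen after seeing the data were limma-voom on the recovered fragments, removal of the GC and length trend, leaving out BMP8B replicates 2 and 4, thinning to the smallest fragment total and leaving out small RNA rows.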

Results

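Gene expression was measured by RNA sequencing in HTR8/SVneo cells, a line made from human first-trimester trophoblast, the epithelial lineage of the placenta, and immortalised with the SV40 large T antigen. Cells left untreated (control, n = 4) were compared with cells given BMP8B, a secreted ligand of the bone morphogenetic protein family, for 24 h (n = 4). The comparison asks which transcripts of trophoblast cells differ after exposure to this ligand. The deposited values were fragments per kilobase of transcript, scaled to the library's fragment total (FPKM). The steps between low values gave 14.28 to 15.05 M fragments per control library and 14.88 to 16.60 M per BMP8B library. Of 29458 rows, 13937 had a mean of at least 0.5 FPKM and were tested. The sources used here do not say whether the 4 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

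The libraries separated by treatment. The mean Pearson correlation of log2(FPKM + 1) was 0.991 between libraries of one group and 0.982 between libraries of different groups (difference 0.00849; exact permutation test over the 35 splits of the libraries, p = 0.0286, the smallest these libraries can give). On the first principal component, which held 46.9% of the variance, the controls lay between -17.79 and -14.34 and the BMP8B libraries between 8.45 and 25.61. BMP8B replicates 2 and 4, at 25.61 and 19.42, lay farther from the controls than replicates 1 and 3, at 9.2 and 8.45. The spread within the BMP8B group was large. By chi-square per degree of freedom on recovered fragments, BMP8B replicate 1 differed more from BMP8B replicate 2 (15.8) than from control replicate 1 (13.1). Without replicates 2 and 4 the difference in correlation was 0.00598, with the smallest exact p that 6 libraries allow, 0.0667.

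**Figure D1:**
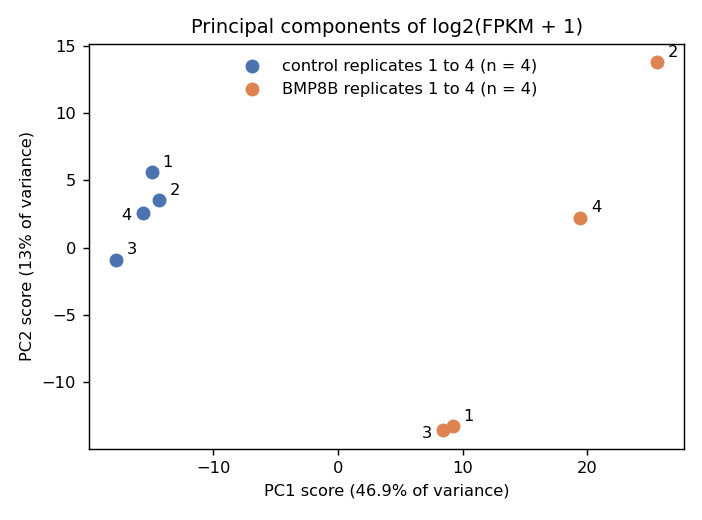
Scores of the 8 libraries on the first (x axis, 46.9% of variance) and second (y axis, 13% of variance) principal component of log2(FPKM + 1), each point a library with its replicate number. The controls lie between -17.79 and -14.34 on the x axis and the BMP8B libraries between 8.45 and 25.61.

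BMP8B treatment was accompanied by many small changes. In the limma test with Benjamini-Hochberg adjustment, 5455 genes passed the threshold of 0.05, or 39.1% of those tested, with 2567 higher and 2888 lower in the treated cells. Protein-coding genes made up 2427 of the higher and 2672 of the lower genes, and long noncoding RNAs 91 and 150. The median absolute log2 change of the called genes was 0.31, or 1.24-fold, and 36 genes changed by at least 1 on the log2 scale. In 5562 genes (39.9%) all 4 BMP8B values lay on one side of all 4 control values, where chance gives 2.86%. This held for each named gene that passed the test except BMPR1A, TGFBR3 and ANGPTL4. Rescaling each library to TPM moved the split of calls to 2008 higher and 3698 lower, so that 35.2% of calls were higher against 47.1% with the values as deposited.

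Calls also went with the base composition and the length of the transcripts. Among the 12962 tested genes with a known GC content, the tercile with the lowest GC held 168 higher and 1718 lower genes, and the tercile with the highest GC held 1534 higher and 238 lower genes. Across genes, the correlation of GC content with a library's distance from the control mean was between -0.26 and 0.21 in the controls, 0.25 and 0.27 in BMP8B replicates 1 and 3, and 0.69 and 0.57 in replicates 2 and 4. By length, the shortest tercile held 1037 higher and 514 lower genes, and the longest 565 and 1325. The correlation with length was -0.081 to 0.111 in the controls and -0.261 to -0.137 in the BMP8B libraries. The 20 gene lists that follow are therefore given with the percentile of its median among 10000 random lists matched on GC content, length and expression. With the trend on GC content and length removed from each library, 2844 genes were higher and 2707 lower.

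**Figure D2:**
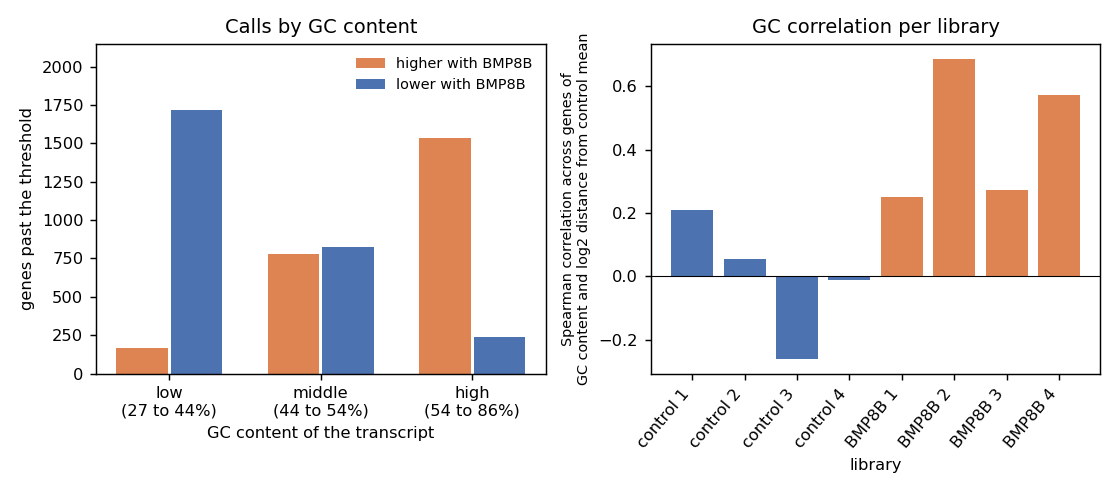
Left, the number of genes past the threshold (y axis) in terciles of the tested genes by GC content of the transcript (x axis, percent), higher with BMP8B in orange and lower in blue; 1718 genes fell in the low tercile and 1534 rose in the high tercile. Right, the Spearman correlation across genes between GC content and the distance of a library from the control mean on the log2 scale (y axis) for each library (x axis), up to 0.69 in BMP8B replicate 2.

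IGFBP5, a binding protein of insulin-like growth factors, rose from 2.09 ± 0.11 to 7.98 ± 0.47 FPKM (mean ± SD, n = 4 per group), or 3.81-fold (adjusted p = 2.67e-06). APLN, which encodes the vasoactive peptide apelin, rose from 3.75 ± 0.20 to 12.03 ± 0.66 FPKM. KISS1, the kisspeptin precursor made by trophoblast, rose from 6.68 ± 0.52 to 18.7 ± 2.5 FPKM. The acid phosphatase gene ACP4 rose 4.64-fold from a low level of 0.69 FPKM, and CEACAM19, of the carcinoembryonic antigen family, rose 2.87-fold. A ranking of protein-coding genes only, on the log2(FPKM + 1) scale and not by fold, was added after the values were seen. On that scale the next largest rises were in CHI3L1 (2.28-fold), the sulfatase SULF2 (2.42-fold) and DIRAS3 (2.66-fold). The TWEAK receptor TNFRSF12A (71.3 ± 3.3 to 148 ± 9.7 FPKM) and the complement receptor C5AR1 (0.46 ± 0.22 to 1.97 ± 0.23 FPKM) followed.

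The largest falls in protein-coding genes on the log2(FPKM + 1) scale included CXCL8, EGR1, NDRG1, CCNG2, CXCL1 and 5 genes with roles in G2 or mitosis. CXCL8, which encodes the neutrophil chemokine interleukin-8, fell from 19.2 ± 2.6 to 8.83 ± 1.55 FPKM (n = 4 per group, adjusted p = 0.000324). The transcription factor EGR1 fell from 28.0 ± 1.5 to 13.5 ± 1.1 FPKM. NDRG1, a gene induced by hypoxia and differentiation, fell from 26.9 ± 4.4 to 12.9 ± 1.6 FPKM. CCNG2, an atypical cyclin linked to cell cycle exit, fell from 19.8 ± 0.5 to 9.59 ± 1.23 FPKM. DLGAP5, CDC25C, HMMR, CENPE and CENPF fell to between 0.50 and 0.55 of their control levels. The long noncoding RNA LOC101927027 fell from 7.32 ± 0.36 to 2.93 ± 0.55 FPKM.

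Rows of small RNA genes supplied 15 of the 19 called falls of at least 1 on the log2 scale and 5 of the 17 such rises, on few fragments. Over the 4 libraries of each group, SNORD11 had 7 fragments in control and 23 in BMP8B, MIR4653 had 6 and 18, SNORD42B 14 and 34, and the mitochondrial tRNA row TRNM 275 and 642. The calls of MIR4653 and SNORD42B ended under some alternatives, among them leaving out BMP8B replicate 4 (log2 changes of 1.08 and 1.04 against 1.14 and 1.13; adjusted p = 0.0542 and 0.0562; over all alternatives 0.00858 to 0.117 and 0.00820 to 0.120). In the other direction, SNORD144 had 46 fragments in control and 14 in BMP8B, and MIR7856 had 19 and 4. MIR320E had 13 and 1, a ratio of 13.8 with a 95% exact counting interval of 2.07 to 586, and its call ended without BMP8B replicates 2 and 4 (log2 change -1.65 against -1.92; adjusted p = 0.0564; over all alternatives 0.00317 to 0.0564). TRS-AGA5-1 and MIR580 had 7 and 6 fragments in control and none in BMP8B. With 3 fragments set as a floor for the BMP8B group, they were 2.48-fold and 2.12-fold lower. That floor leaves out the counting error of the control fragments, so the true falls may be smaller. The interval of MIR320E covers counting error only, and libraries enriched for poly(A) RNA do not measure mature small RNAs directly. Other named noncoding rows were LOC105369349 (94 and 245 fragments), LOC107987181 (125 and 45) and LOC100287175 (108 and 41).

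**Figure D3:**
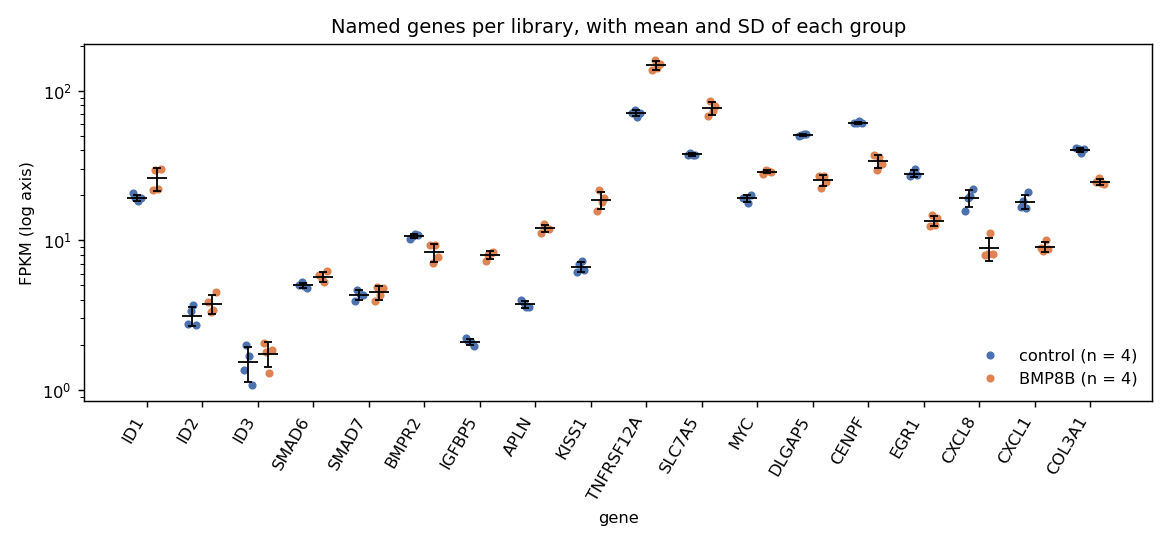
FPKM (y axis, log scale) of 18 named genes (x axis) in each of the 4 control (blue) and 4 BMP8B (orange) libraries, with bars for the mean and SD of each group. IGFBP5 went from 2.09 to 7.98 FPKM and EGR1 from 28.0 to 13.5 FPKM, while the ID2, ID3 and SMAD7 groups overlapped.

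Among ID1, ID2, ID3, SMAD6 and SMAD7, only ID1 passed the test. ID1, an immediate transcriptional target of BMP receptors, rose from 19.3 ± 1.0 to 26.0 ± 4.6 FPKM (n = 4 per group, log2 change 0.39 ± 0.11 SE, adjusted p = 0.0178). Its log2 change was 0.18 without BMP8B replicates 2 and 4 and 0.23 with the GC and length trend removed, and it passed under all alternatives (adjusted p 0.00553 to 0.0496). The related ID2 was at 3.14 ± 0.46 and 3.78 ± 0.55 FPKM (adjusted p = 0.134). ID3, in the higher of its rows, was at 1.53 ± 0.40 and 1.75 ± 0.33 FPKM (adjusted p = 0.469). The inhibitory SMADs did not pass either, with SMAD6 at 5 ± 0.19 and 5.72 ± 0.44 FPKM (adjusted p = 0.0531) and SMAD7 at 4.31 ± 0.32 and 4.48 ± 0.46 FPKM (adjusted p = 0.678). Of the 18 tested genes of the BMP-SMAD target list, 6 rose and none fell (4 and 0 adjusted over the list alone). The rises included the antagonists NOG (1.499-fold) and BAMBI (1.46-fold) and the homeobox gene MSX1 (1.254-fold). The list did not pass the camera test (median log2 change 0.13, adjusted p = 0.104), and its median lay at percentile 95.7 of matched lists. It passed without a filter on low values (adjusted p = 0.0419; 0.0419 to 0.577 over the camera alternatives). The rises of NOG and MSX1 no longer passed with the GC and length trend removed (adjusted p = 0.0931 and 0.0804; over all alternatives, 0.00388 to 0.0931 for NOG and 0.00764 to 0.0804 for MSX1). With 2 libraries fewer, without BMP8B replicates 2 and 4, BAMBI did not pass (adjusted p = 0.0559; 0.00719 to 0.0559 over all alternatives) at an unchanged log2 change of 0.40, nor did MSX1 (adjusted p = 0.0717) at 0.21 against 0.28.

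BMPR2, the type II BMP receptor, fell from 10.7 ± 0.4 to 8.34 ± 1.15 FPKM (log2 change -0.33, adjusted p = 0.0125). It passed under all alternatives (adjusted p 0.00135 to 0.0398), with a log2 change of -0.10 when the GC and length trend was removed and -0.18 without BMP8B replicates 2 and 4. BMPR1A was at 12.4 ± 0.5 and 10.8 ± 1.0 FPKM with overlapping groups (adjusted p = 0.0413). The type I receptor ACVR1 was at 4.53 ± 0.39 and 4.51 ± 0.11 FPKM (adjusted p = 0.962). BMP8B messenger RNA itself rose from 3.37 ± 0.29 to 4.29 ± 0.38 FPKM (adjusted p = 0.0140; 0.0725 without BMP8B replicates 2 and 4, at a log2 change of 0.22 against 0.28, and 0.00433 to 0.0725 over all alternatives). Of 16 tested receptor and SMAD genes 2 rose and 5 fell (2 and 5 adjusted over the list alone). TGFBR2 rose 1.22-fold, and SMAD1 and TGFBR3 fell to 0.87 and 0.74 of control. The list did not pass (median -0.16, adjusted p = 0.237), and matched lists had a median of -0.13, so that it lay at percentile 29.8. Its median was -0.10 without BMP8B replicate 2 and -0.01 with the GC and length trend removed. With the GC and length trend removed, the calls of BMPR1A, TGFBR3 and SMAD1 ended, and the log2 change of SMAD1 went from -0.17 to 0.0037. Leaving out single libraries also ended these calls, with log2 changes of -0.15 to -0.19 for BMPR1A (-0.20 with all libraries), -0.26 to -0.28 for TGFBR3 (-0.30) and -0.15 to -0.16 for SMAD1.

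Targets of TGF-beta and activin went both ways. Of 21 tested genes, 7 rose and 5 fell (7 and 6 adjusted over the list alone). SERPINE1, the plasminogen activator inhibitor, rose from 14.9 ± 0.8 to 21.6 ± 0.6 FPKM, CTGF from 77.4 ± 6.6 to 120 ± 4.9 FPKM and PMEPA1 from 3.42 ± 0.14 to 4.71 ± 0.06 FPKM, while the matrix protein gene TGFBI fell from 120 ± 0.6 to 101 ± 2.8 FPKM. The list as a whole did not pass (adjusted p = 0.351) and lay at percentile 58.0 of matched lists.

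Genes of the G2 and M phases of the cell cycle fell together. Of 40 tested members, 37 fell and 1 rose (38 and 1 adjusted over the list alone), with a median log2 change of -0.46. DLGAP5, a spindle assembly factor, fell from 50.9 ± 0.9 to 25.2 ± 2.1 FPKM (n = 4 per group, adjusted p = 2.69e-05). The mitotic kinesin KIF20A fell from 85.4 ± 2.2 to 53.7 ± 2.2 FPKM, the checkpoint kinase BUB1B from 57.4 ± 0.3 to 36.7 ± 2.0 FPKM and TPX2, an activator of Aurora A, from 169 ± 3.0 to 109 ± 7.1 FPKM. The list passed the camera test with the preset correlation of 0.01 (adjusted p = 2.34e-17) but not with an estimated correlation (adjusted p = 0.0821). Its median lay below all of the 10000 matched random lists (percentile 0).

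S phase genes did not share that fall. Of 34 tested, 11 rose and 2 fell (11 and 2 adjusted over the list alone), with a median log2 change of 0.09 (camera adjusted p = 0.00736, and adjusted p = 0.187 with an estimated correlation). The uracil glycosylase UNG rose from 74.8 ± 1.5 to 94.3 ± 2.5 FPKM and the flap endonuclease FEN1 from 145 ± 1.0 to 179 ± 6.2 FPKM. The transcription factor E2F1 rose from 39.4 ± 1.0 to 53.4 ± 3.5 FPKM and the replication licensing factor CDC6 from 64.8 ± 1.3 to 77.9 ± 2.6 FPKM. The log2 change of E2F1 was 0.43, and 0.26 with the GC and length trend removed. The S phase list also lost its camera call under quantile normalization (median 0.04, adjusted p = 0.0713, and 0.000174 to 0.187 over the camera alternatives). The median of the list was 0.03 after rescaling to TPM and lay, as deposited, at percentile 98.0 of matched lists.

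Genes of ribosome production rose. Of 32 tested genes of MYC and ribosome biogenesis, 25 rose and none fell (25 and 0 adjusted over the list alone), with a median log2 change of 0.40 (camera adjusted p = 2.35e-12; adjusted p = 0.0211 with an estimated correlation; percentile 100 of matched lists). The nucleolar assembly factor RRS1 rose from 21.6 ± 0.5 to 38.1 ± 1.6 FPKM and NOP56 from 110 ± 1.4 to 161 ± 3.6 FPKM. The RNA methyltransferase NOP2 rose from 41.7 ± 1.2 to 67.2 ± 2.9 FPKM and NOLC1 from 61.8 ± 1.2 to 84.8 ± 2.1 FPKM. MYC itself rose from 19.1 ± 1.0 to 28.8 ± 0.6 FPKM.

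Of 56 tested genes for cytosolic ribosomal proteins, 41 rose and none fell (46 and 1 adjusted over the list alone), with a median log2 change of 0.21. RPS11 rose from 1351 ± 63 to 1961 ± 174 FPKM and RPL27 from 462 ± 23 to 636 ± 47 FPKM. RPS4X rose from 1353 ± 22 to 1567 ± 38 FPKM and RPL4 from 1293 ± 23 to 1495 ± 32 FPKM. The list passed the camera test (adjusted p = 1.86e-11) but not with an estimated correlation (adjusted p = 0.218); matched lists had a median of 0.09, and this list lay at percentile 100. Ribosomal protein genes have many processed pseudogenes, and how shared fragments were assigned is not given in the sources used here, so their levels are uncertain. Under quantile normalization the median of the list was 0.06, the log2 change of RPS11 went from 0.53 to 0.33, and the rises of RPS4X and RPL4 no longer passed.

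Of 27 tested genes of the integrated stress response controlled by the transcription factor ATF4, 12 rose and 2 fell (13 and 3 adjusted over the list alone), with a median log2 change of 0.23 (camera adjusted p = 0.000214; adjusted p = 0.0413 with an estimated correlation; percentile 100). The amino acid transporter SLC7A5 rose from 37.6 ± 0.7 to 76.6 ± 7.8 FPKM and its partner chain SLC3A2 from 59.0 ± 1.9 to 92.8 ± 6.0 FPKM. The serine synthesis gene PSAT1 rose from 31.2 ± 1.4 to 45.7 ± 2.3 FPKM and the tryptophanyl-tRNA synthetase WARS from 35.6 ± 0.8 to 44.1 ± 0.6 FPKM. The 2 falls were in PSPH, also of serine synthesis (log2 change -0.19, adjusted p = 0.0112), and STC2 (-0.32, adjusted p = 0.00298), and the cystine transporter SLC7A11 did not pass (0.13, adjusted p = 0.332). The stress effectors DDIT3 (log2 change 0.09, adjusted p = 0.332), CHAC1 (0.03, adjusted p = 0.746) and TRIB3 (0.15, adjusted p = 0.0997) did not pass either; these 6 genes were named after their values were seen. Without a filter on low values the median of the list was 0.15.

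Targets of the coactivator YAP and its partner transcription factors, the TEADs, at the end of the Hippo pathway, rose. Of 22 tested, 14 rose and 1 fell (15 and 2 adjusted over the list alone), with a median log2 change of 0.25. The list passed the camera test (adjusted p = 5.51e-05), also with an estimated correlation (adjusted p = 0.0413), and lay at percentile 100 of matched lists. The matricellular gene CYR61 rose from 61.7 ± 1.6 to 91.9 ± 1.7 FPKM and FJX1 from 6.71 ± 0.49 to 11.2 ± 0.4 FPKM. ANKRD1 rose from 6.30 ± 0.44 to 11 ± 0.6 FPKM and AMOTL2 from 30.4 ± 0.4 to 46.9 ± 3.3 FPKM. Of 13 Wnt targets, 7 rose and 1 fell (8 and 2 adjusted over the list alone). The rises included cyclin D1 (CCND1), from 37.6 ± 1.2 to 60.9 ± 3.2 FPKM, the Wnt antagonist DKK1, from 72.7 ± 1.1 to 102 ± 7.1 FPKM, and the ligand WNT5B, from 4.44 ± 0.46 to 6.81 ± 0.82 FPKM. The list passed the camera test (median 0.25, adjusted p = 0.00553; percentile 99.97) but not with an estimated correlation (adjusted p = 0.0821), and MYC is a member of this list too. Its median depended on the low genes, from 0.04 without a filter on low values to 0.50 with a mean of at least 5 FPKM.

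Cholesterol synthesis genes fell: 10 of 25 fell and 1 rose (14 and 2 adjusted over the list alone), with a median log2 change of -0.20 (camera adjusted p = 0.00550, and adjusted p = 0.0821 with an estimated correlation; percentile 0). LPIN1, a phosphatidate phosphatase that responds to sterols, fell from 19.8 ± 0.8 to 12.6 ± 0.6 FPKM and HSD17B7 from 15.2 ± 0.2 to 10.6 ± 0.5 FPKM. Mevalonate kinase (MVK) fell from 20.1 ± 0.9 to 14.0 ± 1.0 FPKM and squalene synthase (FDFT1, in the higher of its rows) from 16.0 ± 0.4 to 12.3 ± 0.4 FPKM.

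Interferon-stimulated genes showed 15 falls and 5 rises among 27 tested (15 and 5 adjusted over the list alone), with a median log2 change of -0.21. IFIT1 fell from 2.63 ± 0.20 to 1.09 ± 0.18 FPKM, STAT2 from 21.6 ± 1.1 to 15.9 ± 0.6 FPKM and DDX60 from 2.31 ± 0.11 to 1.41 ± 0.13 FPKM, whereas IFITM2 rose from 82.3 ± 4.3 to 102 ± 5.2 FPKM. With the GC and length trend removed, the log2 change of DDX60 went from -0.46 to -0.26 and that of IFITM2 from 0.31 to 0.17. The list did not pass the camera test (adjusted p = 0.0610; 0.00536 to 0.826 over the camera alternatives). Its median was -0.10 without a filter on low values and -0.04 with a mean of at least 5 FPKM. As tested, the median lay at percentile 0.02 of matched lists. Inflammatory genes controlled by NF-kB went both ways, with 8 of 25 higher and 7 lower (9 and 7 adjusted over the list alone; camera adjusted p = 0.877; percentile 15.3). Alongside CXCL8, the chemokines CXCL1 and CXCL6 fell from 18.1 ± 2.0 to 9.04 ± 0.67 and from 26.0 ± 2.7 to 14.4 ± 1.5 FPKM, while the acute phase gene SAA1 rose from 1.88 ± 0.50 to 4.64 ± 0.18 FPKM.

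Of 27 tested matrix proteases and inhibitors, 11 rose and 6 fell (13 and 7 adjusted over the list alone; camera adjusted p = 0.111; percentile 99.4). The urokinase gene PLAU rose from 25.9 ± 2.4 to 40.1 ± 1.8 FPKM, the collagenase MMP1 from 73.8 ± 4.1 to 108 ± 7.0 FPKM and the protease inhibitor TIMP1 from 25.5 ± 1.1 to 34.96 ± 2.8 FPKM. Of 23 mesenchymal genes 5 rose and 8 fell (5 and 8 adjusted over the list alone; adjusted p = 0.721; percentile 21.3). The thrombospondins THBS1 and THBS2 rose 1.41-fold and 1.36-fold, and vimentin (VIM) and ZEB1, a repressor of epithelial genes, fell to 0.77 and 0.61 of control.

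Marker lists of trophoblast types did not pass as lists. Many markers were absent from the deposited rows or below the filter. Tested were 16 of 24 extravillous, 11 of 35 syncytiotrophoblast and 18 of 26 cytotrophoblast and stem markers. HLA-G, GCM1, TP63 and ELF5 were not among them, so these lists say little about trophoblast identity. Of 16 extravillous trophoblast markers 4 rose and 3 fell (5 and 4 adjusted over the list alone; adjusted p = 0.628; percentile 62.9). TIMP3 rose 1.38-fold, and FN1 and ADAM12 fell to 0.81 and 0.60 of control. Of 11 syncytiotrophoblast markers 4 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.194; percentile 71.5). KISS1, SDC1 (50.7 ± 1.5 to 69.5 ± 3.1 FPKM), TFPI2 (1.33-fold) and MFSD2A (1.47-fold) were among the rises. Of 18 cytotrophoblast and trophoblast stem markers 8 rose and 3 fell (9 and 3 adjusted over the list alone; adjusted p = 0.0615; percentile 96.8). The rises included KRT18 (201 ± 4.3 to 275 ± 25 FPKM), TEAD4 (1.48-fold), CCND3 (1.302-fold) and TFAP2A (1.28-fold). Of 30 immediate early and MAPK feedback genes 12 rose and 6 fell (12 and 6 adjusted over the list alone; adjusted p = 0.194; percentile 74.1). FOS fell to 0.56 of control along with EGR1, and the phosphatase DUSP1 and the transcription factor ETV4 rose 1.66-fold and 1.32-fold. Markers of villous fibroblasts, another cell type of the placenta, moved apart, with 3 of 13 higher and 3 lower (3 and 3 adjusted over the list alone; adjusted p = 0.978; percentile 91.0). IGFBP5 rose, and COL3A1 fell from 40.4 ± 1.4 to 24.7 ± 1.1 FPKM, PDGFRB to 0.71 of control and DCN from 0.82 ± 0.14 to 0.20 ± 0.06 FPKM. With the GC and length trend removed, calls were kept at smaller log2 changes for ZEB1 (-0.59 to -0.38), FN1 (-0.31 to -0.16), ETV4 (0.39 to 0.24) and DCN (-0.60 to -0.39).

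**Figure D4:**
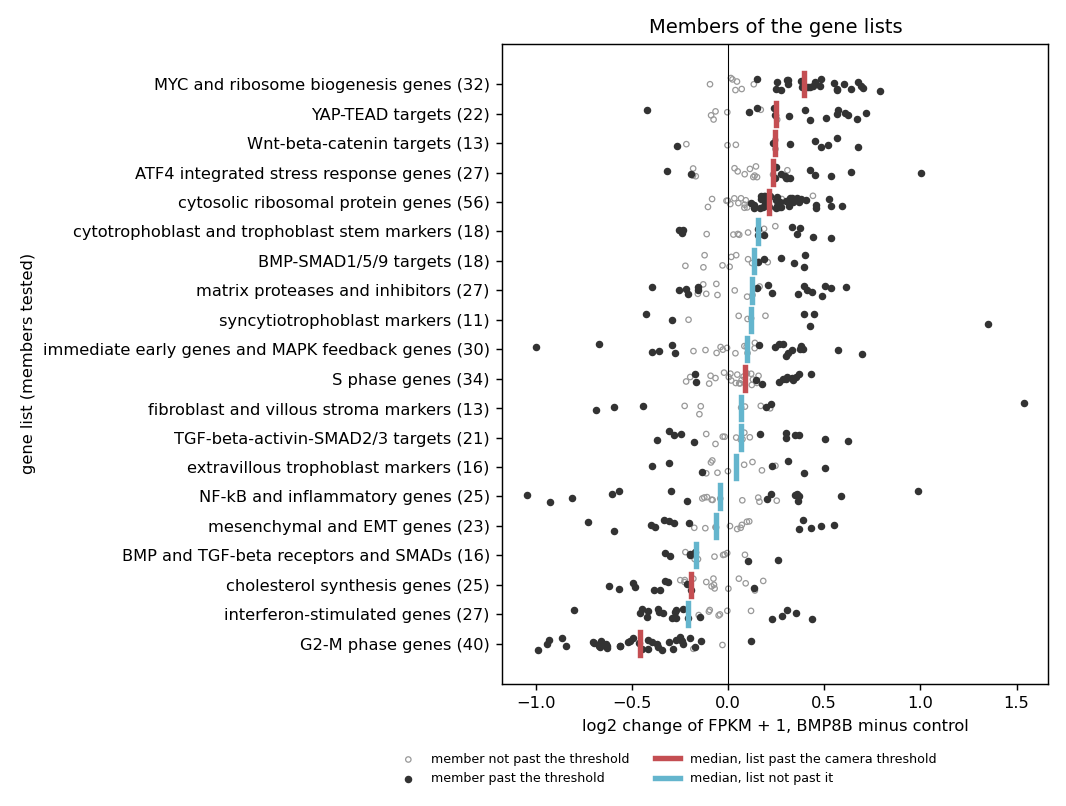
Log2 change of FPKM + 1, BMP8B minus control (x axis), of each tested member of 20 gene lists (y axis, number of members in parentheses), filled points past the threshold and open points not, with a bar at each list's median that is red where the list passed the camera test. The medians run from -0.46 for G2-M phase genes to 0.40 for MYC and ribosome biogenesis genes.

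In all, 8 of 37 tested lists passed the camera test with the preset correlation, and 3 did with an estimated correlation, namely those of MYC and ribosome biogenesis, YAP and TEAD targets, and the ATF4 response.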

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

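The test of fewer cycling cells, the removal of the GC and length trend and the thinning of libraries were chosen only after the results of the comparison were seen.

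A library stood apart from the other 3 of its group in 10 of 230 groups of 4 values, by the ratio of its gap to the group's range (Dixon's ratio); chance gives about 1 in 20, or about 12. In the BMP8B libraries, replicate 3 was above the others for CXCL8, at 11.15 against 7.999 to 8.082 FPKM (ratio 0.974), and held the only fragment of MIR320E (ratio 1.0). In the controls, replicate 1 was below the others for BMPR1A (11.75 against 12.64 to 12.7 FPKM, ratio 0.938) and above them for CDC25C (ratio 0.878). Control replicate 2 was below the others for RPL4 (ratio 0.838) and FN1 (ratio 0.932). Control replicate 3 was below them for SDC1 (ratio 0.969) and above them for CENPF (ratio 0.895), and control replicate 4 was below them for BAMBI (ratio 0.861) and above them for PLAU (ratio 0.881).

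The first pattern is the number of genes past the threshold, 5455. Of the 35 ways to split the 8 libraries into groups of 4, 1 gave as many, the real one, and the highest of the others gave 1 gene. A share of 1 of 35 is the smallest these libraries can give. The other splits mix libraries of both groups, which raises the spread within a group, so their low counts add little beyond that rank. With the trend on GC content and length removed from each library, 74.1% of the calls that could be tested were kept in the same direction, so that trend is not the whole cause. Thinning all libraries to the smallest fragment total kept 96.4%. The totals lay close, from 14.28 to 16.60 M, and FPKM divides by them, so this test could hardly have come out otherwise and decides little. An effect of BMP8B may account for the rest, as a hypothesis, but differences in handling between the cultures of the 2 groups go with the treatment and stay open.

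The second pattern is the distance of BMP8B replicates 2 and 4 from replicates 1 and 3. As a share of the distance between the groups on the first component, their gap was 0.448 over the genes with a GC content. It fell to 0.119 after the GC and length trend was removed. The trend was fitted to each library, so any difference that goes with GC content, technical or biological, would give such a fall. Library size did not follow the pattern: replicate 4 had 14.92 M fragments, between replicates 1 and 3 at 14.88 and 16.26 M. A GC bias of library preparation or amplification is a candidate explanation, and no biological explanation was tested.

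The third pattern is the fall of G2-M phase genes. A GC and length trend does not account for it, since the median lay at percentile 0 of matched random lists; the same test placed the rise of MYC and ribosome biogenesis genes at percentile 100. If fewer cycling cells lowered S phase genes too, their median would fall. Their median log2 change was 0.0897 (0.0339 to 0.130 over the alternatives), with 11 members higher and 2 lower. The S phase list did not pass camera with an estimated correlation (adjusted p = 0.187). Whether S phase transcripts follow the share of cycling cells in this line, immortalised with SV40 large T antigen, was not tested, so that account is not excluded. For G2-M genes, 1 of 35 splits, the real one, gave a camera p as small, the smallest share these libraries can give. Fewer cycling cells, a shift in the share of cells in G2 and M, or lower expression of these genes in each cell may account for the fall. These data do not part these accounts.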

How the results depend on the processing

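Of 107 named genes past the threshold, 95 passed it in the same direction under every alternative that tested them. Most of them were named for large changes or small p in these same values, so this share does not describe all calls. Of all 5455 calls, 3787 were kept in the same direction without BMP8B replicates 2 and 4, and 4014 without BMP8B replicate 4. The 8 lists past the threshold kept their direction under all alternatives. List medians moved by more than 1.5 times for Wnt targets (0.04 to 0.50), cytosolic ribosomal proteins (0.06 to 0.25), S phase genes (0.03 to 0.13) and ATF4 genes (0.15 to 0.25). Among lists not past it, they moved as far for receptors and SMADs (-0.24 to -0.01), interferon-stimulated genes (-0.27 to -0.04), BMP-SMAD targets (0.06 to 0.18), BMP ligands and antagonists (0.05 to 0.25) and others. Removal of the GC and length trend lowered log2 changes by more than 1.5 times, with the call kept, for ID1 (0.23), BMPR2 (-0.10), E2F1 (0.26), DDX60 (-0.26), IFITM2 (0.17), FN1 (-0.16), ZEB1 (-0.38), ETV4 (0.24) and DCN (-0.39), as quantile normalization did for RPS11 (0.33). Leaving out each library in turn gave 1956 to 2686 higher genes, 2107 to 2986 lower genes, 8 to 11 lists and a difference in correlation of 0.00725 to 0.00984. The counts of calls moved by more than 1.5 times only with stricter thresholds: at an adjusted p under 0.01 they were 1471 higher and 1557 lower, and with an absolute log2 change of at least 1 they were 17 and 19. Lists past the threshold numbered 3 with an estimated correlation and 22 with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. Without BMP8B replicates 2 and 4, a choice made after seeing the data, 2130 genes were higher and 2283 lower, and the difference in correlation was 0.00598 with the smallest p possible, 0.0667. With the GC and length trend removed, also chosen after, the log2 change of SMAD1 reversed to 0.0037 (adjusted p = 0.968; over all alternatives 0.00702 to 0.968), and BMPR1A, TGFBR3, NOG and MSX1 no longer passed; apart from the removal of the trend the cause was not tested. BMPR1A lost its call under 12 alternatives, among them the removal of control replicates 2, 3 or 4 and of BMP8B replicates 2 or 4 (adjusted p 0.0180 to 0.514), and TGFBR3 under 8, among them the removal of control replicates 1 or 2 and of BMP8B replicates 1 or 4 (adjusted p 0.00368 to 0.136). SMAD1 was lost without control replicates 1 or 3 (adjusted p = 0.0548 and 0.0629), MIR4653 without control replicate 4 or BMP8B replicate 4 (0.0522 and 0.0542; over all alternatives 0.00858 to 0.117), and SNORD42B without BMP8B replicate 4 (0.0562; over all alternatives 0.00820 to 0.120). Without BMP8B replicates 2 and 4, BAMBI and MIR320E no longer passed, with 2 libraries fewer and log2 changes of 0.40 and -1.65 against 0.40 and -1.92 (adjusted p = 0.0559 and 0.0564; over all alternatives 0.00719 to 0.0559 and 0.00317 to 0.0564). SMAD6 passed under 5 alternatives (adjusted p 0.0215 to 0.344), 1 of them without BMP8B replicate 3 (0.0322). Interferon-stimulated genes passed as a list under 6 camera alternatives, including the removal of the GC and length trend (adjusted p = 0.0298; over the camera alternatives 0.00536 to 0.826), and without control replicate 3 or BMP8B replicate 4. Cytotrophoblast markers passed under 4, including without control replicate 3 or BMP8B replicates 1 or 4 (0.0438, 0.0493 and 0.0464; over the camera alternatives 0.0438 to 0.218), and angiogenesis factors under 2, including without control replicate 3 (0.0385; over the camera alternatives 0.0385 to 0.218). By fry, which does not compare with other genes, these 3 lists and that of BMP-SMAD targets had adjusted p of 6.18e-05, 0.00154, 0.000439 and 0.00400. The limma-voom test on recovered fragments, whole for 100% of rows above 0, called 2731 higher and 3261 lower genes.

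Pairing of the libraries by the shared replicate numbers was not shown. Deviations of same-numbered libraries correlated at -0.024, 0.056, 0.102 and -0.01. While 4 of 8 libraries correlated best with their own number, no chance level was computed for that count, so a weak pairing stays open. With the replicate number as a block, 2361 genes were higher, 2582 lower and 8 lists past the threshold. Depth limits the rows of small RNA genes, several of which rest on under 50 fragments per group, and without all small RNA rows 2692 genes were higher and 3032 lower.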

Other observations

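Further lists, none past the camera test, had members that changed. Among 14 tested BMP ligands and antagonists, 6 rose and none fell (median log2 change 0.17, adjusted p = 0.107). CHRD, which encodes the BMP antagonist chordin, rose from 3.29 to 5.09 FPKM (adjusted p = 0.00211), the activin antagonist FSTL3 from 15.3 to 19.1 FPKM and GDF15 from 5.65 to 7.77 FPKM; these and the other genes of this part were chosen after their values were seen. Of 22 angiogenesis factors 9 rose and 4 fell (adjusted p = 0.0679), with PDGFA rising from 6.63 to 9.13 FPKM, PDGFB from 1.75 to 2.70 FPKM and VEGFA from 7.07 to 9.12 FPKM, and PGF falling to 0.68 of control and ANGPTL4, with overlapping groups, to 0.51. Hypoxia and glycolysis genes split, with 6 of 33 higher and 11 lower (adjusted p = 0.566): KDM3A (log2 change -0.52), CA9 (-0.68) and PGK1 (-0.33) fell with NDRG1, and SLC2A1 (0.41) and PFKP (0.32) rose.

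Higher and lower members of the other lists numbered 2 and 3 of 16 epithelial junction genes, 8 and 7 of 31 collagen and matrix genes, 4 and 9 of 29 integrin and focal adhesion genes, 9 and 3 of 31 genes of p53 and apoptosis, 3 and 3 of 13 antigen presentation genes and 1 and 4 of 28 genes of the unfolded protein response. They numbered 7 and 6 of 23 fatty acid and thermogenic genes, 6 and 6 of 38 nuclear oxidative phosphorylation genes, 7 and 3 of 22 antioxidant genes of NRF2, 7 and 2 of 16 Notch genes, 3 and 6 of 21 heat shock genes and 1 and 4 of 15 histone genes. Of 9 nuclear-retained and small RNA genes used as signs of RNA quality, 2 rose and 1 fell, and these 13 lists had camera adjusted p of 0.0673 to 0.909; the nuclear RNA NEAT1 fell by 0.49 on the log2 scale (adjusted p = 7.42e-05). Among markers of other cell types, 3 of 6 endothelial genes (adjusted p = 0.0963) and 2 of 3 immune genes (too few for a test) rose, and none fell. The fixed list of erythroid genes had 0 tested members, with 9 of 14 symbols matched to a row. Of the 15 symbols in the fixed list of mitochondrially encoded genes 0 matched a row, so that list says nothing about their levels. Mitochondrial tRNA genes such as TRNM, outside that list, were tested as single genes. The endothelial gene ESAM rose from 1.21 to 2.38 FPKM, and the immune genes CD68 and ITGB2 from 18.5 to 27.2 and from 1.019 to 2.25 FPKM. The median and the camera direction differed in sign for the NF-kB, unfolded protein response, fatty acid and fibroblast lists.

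Chance could not be excluded for the number of lists past the threshold. Of the 35 splits of the libraries, 9 gave at least the real 8 lists, and the highest of the others gave 13. Each of the others that reached 8 set 3 libraries of one group against 3 of the other, and so kept part of the treatment contrast. Splits with 2 libraries of each group on either side gave at most 3 lists. The number of lists therefore decides little about chance. The preset correlation of camera is a candidate cause, since with an estimated correlation 3 lists passed. List by list, only the real split gave a camera p as small for the G2-M, MYC, YAP and TEAD, and ATF4 lists. For cholesterol synthesis genes 2 of 35 did, for Wnt targets 3, for S phase genes 5 and for cytosolic ribosomal proteins 5. By this measure chance was not excluded for the last 4 lists, though some of those splits may also keep part of the treatment contrast. By the size of the list median, 1 of 35 splits, the real one, was as large for each of the 8 lists.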
